A study of Ictalurus punctatus and Ictalurus punctatus x Ictalurus furcatus with 18 samples.

How the data were processed

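Liver RNA of 3 types of fingerling catfish was sequenced after a 6 week trial in which the water temperature cycled daily. The low regime ran between 27 and 31 °C and the high regime between 32 and 36 °C, per the labels. The types were the Red River strain of channel catfish, the Delta Select strain of channel catfish, and the Delta Select hybrid, a cross between channel and blue catfish. Each of the 18 libraries was a pool of RNA from 3 fish of 1 tank, per the labels' protocols, so a library stands for a tank and not for a fish. Each of the 6 groups (type by temperature) held 3 libraries. Libraries H1 to H9 came from the high regime and L1 to L9 from the low regime. These codes number libraries within a regime across the types, so nothing was paired. Libraries were made with an Illumina TruSeq version 2 kit and read as single ends of 50 bases, per the labels' protocols.

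The authors deposited raw read counts for 144746 assembled transcripts in 1 table, with 1 column per library. A further row of that table names no transcript and held 24.2% to 25.6% of each library's reads, and it was left out of library sizes and tests. A second deposited table holds a normalized signal, the raw count divided by 1 size factor per library. The ratio of both tables was constant within each library. It equalled the median-of-ratios size factor computed over all rows, the row with no transcript included, to a relative difference of at most 1.6e-15. The normalized table was used for that check alone. Bowtie2 2.1.0, DESeq 1.12.1 and R 3.1.0 are listed in the submitters' processing notes, with no role given. The assembler, the counting tool, the treatment of reads that fit several transcripts and the use of strand are not given in the sources used here. All 144746 identifiers have the form of a k-mer size, from 50 to 94, and a number. None of them matched the reference gene table of channel catfish (assembly Coco_2.0, 32344 genes), which gives 0 matches. Transcripts are therefore named by identifier, and their genes, positions and functions were not determined here. Transcripts of 1 gene, of paralogs and of the 2 parental species can share reads, so the count of a single identifier is uncertain in how such reads were divided. A call is a transcript, not a gene.

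Reads on transcripts came to between 36242058 and 76146359 per library. All 18 pairs of libraries within groups were compared by a chi-square test of their counts, which gave between 9.58 and 46.2 per degree of freedom, so no pair agreed within sampling noise. For numbers of detected transcripts, every library was thinned to 36242058 reads.

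Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood fit with robust set to true) in R 4.3.3, with TMM scaling and 1 mean per group over all 18 libraries, so that the groups shared an estimate of the spread. The filter filterByExpr over the 6 groups, with a minimum count of 10 and a minimum total of 15, kept 96799 transcripts and left out 47947. P-values were adjusted by the method of Benjamini and Hochberg, and a transcript with an adjusted p under 0.05 is called. Temperature contrasts are high minus low, in each type and averaged over the 3 types. Type contrasts were averaged over both temperatures and also made within each. Differences in temperature response between types were tested by a joint interaction test and by pairwise interactions. Standard errors of log2 fold changes were taken from the F statistic. Levels are in CPM, computed from the deposited counts with TMM scaling and given as mean ± SD. Where a group held few reads, a ratio of summed reads is given with its 95% exact interval, which covers counting error only and not the spread between tanks.

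At most 2 transcripts that rose and 2 that fell were named per contrast, by a rule set before the data were examined. They are those of the largest change among called transcripts with a mean log2 CPM of at least 3. For the averaged temperature effect the mean also had to change in the same direction in each type. For the other contrasts the libraries of the compared groups had not to overlap, within each temperature for type contrasts. Gene lists set at the same time, from heat-shock proteins to markers of other liver cell types, were not applied, because the identifiers carry no gene names.

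The test was checked on counts simulated from the 96799 transcripts, with 100 changed 2-fold and 100 changed 4-fold. It recovered 99% and 100% of these for the averaged temperature effect, 34% and 99% for Delta Select temperature, 90% and 100% for hybrid against Red River, and 8% and 89% for the joint interaction. The changed transcripts were drawn from the more abundant ones only. All groups were given the same mean level and a spread set by level alone, without differences between types or single aberrant libraries. These settings may make recovery in the real counts lower. In the other direction, few transcripts were changed, so the simulated Delta Select comparison had 139 calls against 12432 in the real one. The cutoff on the adjusted p loosens with more calls, which may make recovery in the real counts higher. Alternatives were DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), DESeq2 size factors in edgeR, and no filter on low counts. Others were a mean of at least 50 reads per library, leaving out the 20 most abundant transcripts, fitting only the compared groups, and leaving out each library of those groups in turn. The data led to further ones: leaving out libraries L3 and L5 together, leaving out pairs of low-temperature libraries in 1 type or in every type, and thinning all libraries to 1 depth. Exact permutation tests of single values per library were made with SciPy 1.17.1. For the size of the temperature response, type names were permuted within each temperature after each type's mean over its 6 libraries was removed. This removal was added after the data were seen, since levels differ between types and widen the permuted values. It makes the test approximate, and the exact test without it gave p = 0.37, 0.61 and 0.3 for transcripts chosen in Red River, Delta Select and hybrid fish.

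The share of hybrid RNA in each library was estimated from 129 hybrid-restricted transcripts, chosen after the data were seen. In these the Red River mean was at most 1% of the hybrid mean and every hybrid library had at least 1 CPM. A library's share is the median, over these transcripts, of its level on a scale from 0 at the Red River mean to 1 at the hybrid mean of the same temperature. A Red River or hybrid library was left out of the mean when its own share was computed. The Delta Select libraries did not enter the choice.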

Results

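Hepatic gene expression was profiled in 18 RNA-seq libraries to ask how catfish types differ in their response to 6 weeks at a high cycling temperature. Each type, Red River channel catfish, Delta Select channel catfish and the Delta Select hybrid of channel and blue catfish, was represented by 3 tank pools at 27 to 31 °C and 3 at 32 to 36 °C. The libraries held between 36242058 (L2) and 76146359 (H3) reads on transcripts. At an equal depth of 36242058 reads, hybrid libraries had reads on more transcripts than channel catfish libraries, with a mean of 121799 against 118279 (exact permutation test, two-sided p = 0.00097, 6 against 12 libraries). The means at the high and the low temperature, 119729 and 119176, gave p = 0.604 by the same exact permutation test (9 against 9 libraries). In hybrids the number rose from 120289 ± 588.2 to 123310 ± 546.6 (SD, n = 3 and 3), with every high-temperature library above every low-temperature library. In the channel strains the direction rested on L3 and L5 or on L6. In Delta Select the high-temperature mean was 118560 ± 933.3, against 120750 in L3, 120075 in L5 and 117671 in L8 at the low temperature. In Red River fish it was 117316 ± 197.2, against 119376 in L6, 116941 in L2 and 116903 in L9. An exact test of 3 libraries against 3 cannot reach p under 0.05, and the difference between the types was not tested.

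The difference between hybrid and channel catfish separated the libraries most, and the temperature came next. The leading principal component of log2 CPM carried 47.1% of the variance and set hybrid libraries, at scores from 160.2 to 181.8, apart from channel catfish libraries. The next carried 12.4% and set all 9 high-temperature libraries, which had negative scores, apart from all 9 low-temperature libraries, which had positive scores. Among libraries labelled Delta Select channel catfish at the low temperature, L8 lay with the channel catfish at -94.42 on the leading component, while L5 lay at 34.33 and L3 at 122.4. The 129 hybrid-restricted transcripts showed the same order. Their median level, on a scale of 0 for Red River and 1 for hybrid fish, was 0.7 in L3 (quartiles 0.572 and 0.917) and 0.284 in L5 (quartiles 0.242 and 0.347). It was 0 in L8 and at most 0.000271 in the Delta Select libraries of the high temperature. The 6 hybrid libraries lay between 0.932 and 1.07, which follows from the choice of transcripts and scale.

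**Figure D1:**
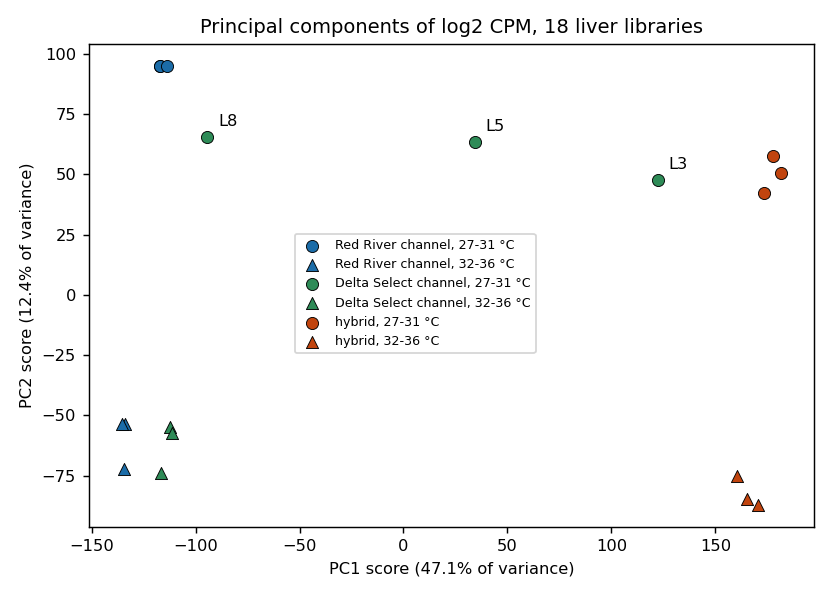
Scores of the 18 liver libraries on the leading principal components of log2 CPM, one point per library, coloured by catfish type, with circles for 27 to 31 °C and triangles for 32 to 36 °C. The horizontal axis carries 47.1% and the vertical axis 12.4% of the variance, and the low-temperature Delta Select libraries L5 and L3 lie at 34.33 and 122.4 on the horizontal axis, between the other channel catfish and the hybrids.

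**Figure D2:**
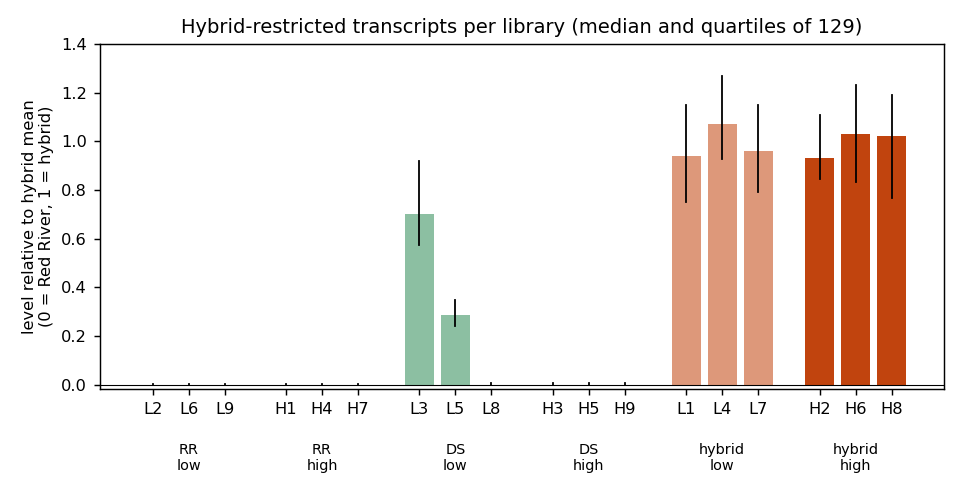
Level of 129 hybrid-restricted transcripts in each library, on a scale of 0 for the Red River mean and 1 for the hybrid mean of the same temperature. Bars are medians over the transcripts and lines join the quartiles, pale bars are the low temperature, and L3 (0.7) and L5 (0.284) stand apart from the other channel catfish libraries, which lie near 0.

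The first comparison asked which transcripts the high temperature changed across all types. The high temperature turned on transcripts that were almost absent at the low temperature. The level of k86:237239 rose from 0.0682 ± 0.0675 to 24.35 ± 15.5 CPM (SD, n = 9 and 9), a ratio of 346 with a counting interval of 236 to 530. The level of k94:1388479 rose from 0.1172 ± 0.0746 to 47.15 ± 32.2 CPM, a ratio of 394 (294 to 540). Both were higher in each of the 9 high-temperature libraries than in any low-temperature library, and their log2 fold changes were 8.81 ± 0.67 (SE) and 8.54 ± 0.61 (edgeR, adjusted p = 1.14e-06 and 5.87e-07). In all, 22 called transcripts had a low-temperature mean under 0.5 CPM and more than 2 CPM in every high-temperature library.

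Changes of smaller size were spread over a large part of the liver transcriptome. Of the 96799 transcripts tested, 10150 rose and 9435 fell, with median log2 fold changes of 0.67 and -0.58. Which direction held more calls depended on the method, with 9477 rises and 10295 falls under DESeq2 size factors, 9729 and 11053 in DESeq2, 7223 and 7995 at a mean of at least 50 reads, and 9723 and 9972 without the 20 most abundant transcripts. Falls also outnumbered rises without any of H1, H2, H3, H5, H7, H8 and L8. Over 2-fold, 2643 rose and 1627 fell, and over 16-fold 75 rose and 2 fell. Of all 96799, without regard to calls, 1356 had all 9 high-temperature libraries above all 9 low-temperature libraries and 551 had them below, where chance gives 0.00206%, or 1.99 transcripts, in each direction. The pair of falls named by the rule rested on library L5. The transcript k66:1845628 had 1655 CPM in L5 and at most 1.579 CPM in any other library, and k58:248466u had 1635 CPM in L5 and at most 1.687 CPM elsewhere. Without L5 their log2 fold changes went from -4.12 to -1.02 and from -3.81 to -0.89. The former lost its call under 18 of 24 alternatives, leaving out L5 among them. The latter stayed called without L5 but lost its call under 14 of 24, in limma-voom and without any of 13 other single libraries. DESeq2 gave neither an adjusted p (log2 fold changes -4.13 and -3.82). Apart from the fit without L5, the log2 fold changes behind these lost calls stayed between -3.81 and -4.43 for the former and between -3.48 and -3.98 for the latter. Without L3 and L5 the averaged effect had 8249 rises and 7188 falls.

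**Figure D3:**
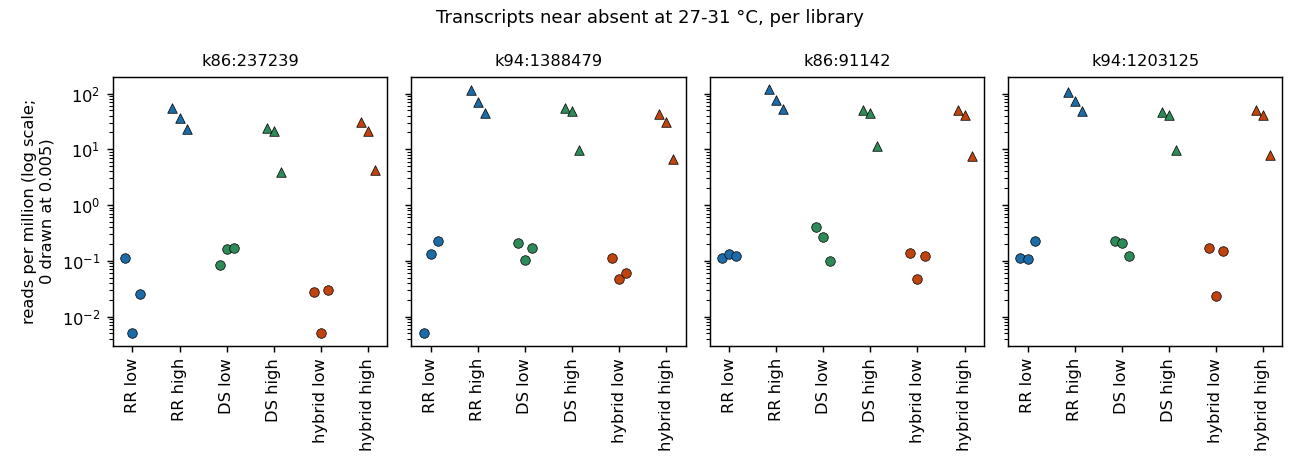
Levels of the transcripts named by the rule as rising with temperature in the average, in Red River or in Delta Select fish, in CPM on a log scale, with one point per library, 3 per group, and values of 0 drawn at 0.005. All high-temperature libraries (triangles) lie above all low-temperature libraries (circles), and k86:237239 has means of 24.35 and 0.0682 CPM at the high and low temperature.

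Within Red River fish the same kind of transcript led the response. The transcript k86:237239 rose from 0.04578 ± 0.0591 to 37.85 ± 15.5 CPM (SD, n = 3 and 3), a ratio of 946 (405 to 2910) that rests on 5 reads at the low temperature. The transcript k86:91142 rose from 0.1228 ± 0.00972 to 82.75 ± 33.6 CPM, a ratio of 688 (417 to 1230). Its high-temperature levels ran close to those of k94:1203125, named below, with 118.8 and 108.5 CPM in H1 and 7.717 and 7.998 CPM in H8. Whether such identifiers come from 1 gene was not determined. Falls were smaller. The transcript k90:1938705 fell from 22.2 ± 5.04 to 2.871 ± 2.14 CPM (log2 fold change -2.96 ± 0.70, edgeR adjusted p = 0.0244) and k66:1866410 from 16.73 ± 3.09 to 2.171 ± 1.7 CPM (-2.96 ± 0.65, adjusted p = 0.0158). Neither of these falls was called with only the Red River libraries fitted, where both log2 fold changes were -2.97. The former was also not called without H1, H4, L2 or L6 (log2 fold changes from -2.57 to -2.91), nor the latter without H1 or H4 (-2.74 and -2.63). In all, 3628 transcripts rose and 2262 fell, a total of 5890. The total was 3463 without H4, 3796 without H7, 3392 without L6 and 3854 without L9, and 8930 with limma-voom.

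In hybrid fish k86:237239 rose as well, from 0.01934 ± 0.0168 to 18.62 ± 13.5 CPM (SD, n = 3 and 3), a ratio of 1020 (282 to 8420) that rests on 2 low-temperature reads. The transcript k86:808971 rose from 0.02785 ± 0.0302 to 99.83 ± 144 CPM, but its level was uneven, at 264.6 CPM in H8, 34.72 in H6 and 0.1648 in H2, and it was not called without H8, L1, L4 or L7 (log2 fold changes from 9.18 to 12.65, against 11.71 with all libraries), in limma-voom (7.92) or with only the hybrid libraries fitted (11.70). In limma-voom and with only the hybrid libraries k86:237239 was not called in hybrids either, at log2 fold changes of 9.17 and 9.78 against 9.81 with all libraries. The transcripts k70:1600491 and k78:1236553 fell in the hybrids. The former went from 145.5 ± 76.4 to 19.66 ± 4.15 CPM (log2 fold change -2.89 ± 0.47, edgeR adjusted p = 0.00398) and the latter from 79.91 ± 38.7 to 11.76 ± 2.29 CPM (-2.77 ± 0.46, adjusted p = 0.00441), and each stayed called under all 14 alternatives tried. Their means were also lower at the high temperature in the other types. In Red River fish they went from 23.85 to 7.955 and from 9.778 to 3.543 CPM. In Delta Select fish, with L3 and L5 included, they went from 50.65 to 6.427 and from 26.44 to 3.038 CPM. The levels of both ran together, with 229.7 and 122.5 CPM in L4 and 15.49 and 9.506 CPM in H8. In all, 1713 transcripts rose and 1142 fell, a total of 2855. The total was 1709 without H6, 1869 without H8, 1483 without L4 and 1683 without L7.

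In fish labelled Delta Select channel catfish, k94:1388479 rose from 0.1601 ± 0.0525 to 38.08 ± 24.8 CPM (SD, n = 3 and 3), a ratio of 257 (170 to 411), and k94:1203125 from 0.1848 ± 0.0547 to 32.38 ± 19.6 CPM, a ratio of 184 (125 to 282). Without L3 and L5 the former was not called (log2 fold change 7.77 against 7.88). The falls of largest size were of transcripts found in single libraries or in hybrids. The transcript k94:98188 had 42.09 CPM in L3, 21.18 in L5 and 0.07366 in L8, against 1 read in all high-temperature Delta Select libraries and at least 43.32 CPM in every hybrid library. Without L3 and L5 its log2 fold change went from -11.31 to -3.20 and it was not called. It was also not called in limma-voom or with only the Delta Select libraries fitted, at -9.84 and -11.40. The transcript k58:1674560 had 1642 CPM in L5 and at most 0.8802 CPM in any other library, and it was not called without L5 (log2 fold change -1.49 against -11.15) or without any of H3, H5 and H9 (-10.67 to -11.97). It was also not called without both L3 and L5 (-1.66), in limma-voom (-10.16) or with only the Delta Select libraries fitted (-11.19), and DESeq2 gave it no adjusted p (-11.18). In all, 5476 transcripts rose and 6956 fell, a total of 12432, of which 108 falls were among the 129 hybrid-restricted transcripts. The total was 7733 without H3, 7127 without H5 and 6104 without L3. Without both L3 and L5, which leaves L8 alone in its group and takes it to vary like the other groups, 1472 rose and 1258 fell, and 1992 transcripts were called in the same direction in both fits. The Delta Select total of 2730 was then the lowest of the types, with 7550 in Red River and 3915 in hybrid fish, whose groups kept all 3 libraries. With only the Delta Select libraries fitted, 2578 were called, and limma-voom called 18659.

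**Figure D4:**
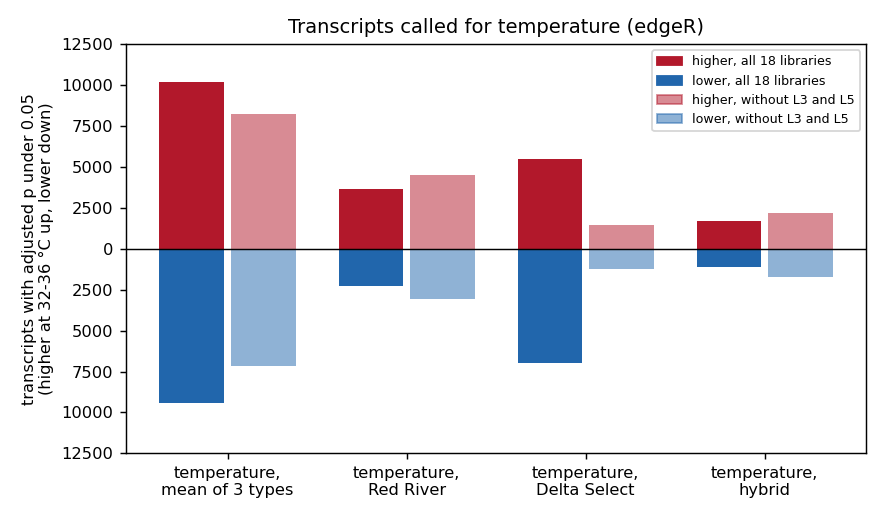
Numbers of transcripts called for temperature (edgeR, adjusted p under 0.05), with rises drawn upwards and falls downwards, for the average and for each type. Dark bars use all 18 libraries and pale bars leave out L3 and L5, which takes the Delta Select rises from 5476 to 1472 and its falls from 6956 to 1258.

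The design also asked whether the types responded differently. The responses largely ran in the same direction, and the types share no library in this comparison. Of the 5890 transcripts called in Red River fish, 91.6% changed in the same direction in Delta Select and 94.4% in hybrid fish. Of the 2855 called in hybrids, 96.9% changed in the same direction in Red River and 95.5% in Delta Select fish. Of the 12432 called in Delta Select, 82.9% did so in Red River and 83.4% in hybrid fish. Red River and hybrid fish had 1761 calls in common in the same direction and 0 in opposite directions, where independent lists would share 91 in the same direction. Red River and Delta Select had 3034 and 8 (368 for independent lists), and Delta Select and hybrid 1979 and 3 (179 for independent lists). A set of 1474 transcripts was called in every type, all in the same direction, with 1129 rises and 345 falls. The Delta Select calls in these overlaps were made with L3 and L5, and the overlaps were not counted without those libraries. Across all transcripts, which are not independent replicates, Spearman correlations of the log2 fold changes were 0.428 for Red River and hybrid, 0.362 for Red River and Delta Select, and 0.373 for Delta Select and hybrid.

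The size of the response was compared on transcripts chosen in the remaining type. On those called in Red River fish, the mean log2 change in the Red River direction was 0.837 in Delta Select and 0.7601 in hybrid fish, a difference of 0.07688 ± 0.062 (SE; permutation test with the type means removed, two-sided p = 0.22, 3 libraries per group). Against L8 alone the Delta Select value was 0.8489. On those called in hybrids it was 1.197 in Red River and 1.094 in Delta Select fish, a difference of 0.1026 ± 0.0953 (p = 0.3 by the same permutation test), and the Delta Select value was 1.115 against L8 alone. On those called in Delta Select it was 0.5617 in Red River and 0.4774 in hybrid fish, a difference of 0.08429 ± 0.0371 (p = 0.035 by the same permutation test, and 0.105 after Benjamini-Hochberg adjustment over these 3 comparisons). The Delta Select list was chosen with L3 and L5 among its libraries. The joint interaction test of edgeR called 0 transcripts, with 10919 at an unadjusted p under 0.05 where 4840 would be reached by chance. The smallest adjusted p was 0.124, for k70:295020, whose log2 fold changes were -0.16 in Red River, 1.83 in Delta Select and -0.08 in hybrid fish, and for k54:2664102, with -0.98, -1.15 and 0.53. Each pairwise interaction also had 0 calls in edgeR, with 11211 (Red River and Delta Select), 10322 (hybrid and Delta Select) and 5619 (hybrid and Red River) at an unadjusted p under 0.05. DESeq2 called 1215 transcripts for the joint interaction, limma-voom 197, and edgeR 53 without L3 and L5. Leaving out a single library gave 3363 calls without L8, 14 without H9, 6 without H3, 1 each without H4, H6 and L2, and 0 without any of the others. Without L8, the low-temperature Delta Select group held only L3 and L5, the libraries that carry hybrid-restricted transcripts. With all libraries, L3 and L5 also enter the joint test and both pairwise interactions with Delta Select.

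The strains of channel catfish were compared across both temperatures. The transcript k62:1348799 was higher in Red River fish, at 52.56 ± 13.5 against 13.72 ± 6.27 CPM in Delta Select fish (SD, n = 6 and 6), with a log2 fold change of 1.96 ± 0.32 (edgeR, adjusted p = 0.00615). The transcript k94:1385314 was higher at 136.1 ± 24.9 against 44.39 ± 22.6 CPM (1.64 ± 0.28, adjusted p = 0.00728). Neither was called without L3 and L5, with log2 fold changes of 1.93 and 1.51 there. The transcripts k86:811921 and k82:1066308 were near absent in Red River fish, at 0.1699 ± 0.0828 and 0.488 ± 0.187 CPM. In Delta Select fish they reached 7.906 ± 4.21 and 35.59 ± 19 CPM at the high temperature (n = 3), and 2.406 and 10.46 CPM in L8. Both were far higher still in hybrids, at 238.1 ± 13.2 and 359.5 ± 36 CPM at the high temperature, and in L3, at 157.9 and 226.1 CPM. They stayed called without L3 and L5, with log2 fold changes of -4.78 and -5.35 against -7.23 and -7.03 with all libraries.

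In all, 1120 transcripts were higher and 1590 lower in Red River than in Delta Select fish, a total of 2710. At the low temperature, where L3 and L5 enter, 4197 differed, and at the high temperature 273, of which 126 were higher and 147 lower in Red River fish. The total fell to 1022 without L3 and L5. It was 1693 without H1, 1728 without H5, 1730 without H7, 1785 without L5, 1544 without L6 and 7178 without L8. The fit without L8 left only L3 and L5 for Delta Select at the low temperature. DESeq2 called 4889, limma-voom 5779, and the fit of only these groups 1656.

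Hybrid fish differed from Red River channel catfish in a large part of the transcripts tested. The transcript k82:1046721 had 47.85 ± 11 CPM in hybrids and 0.01982 ± 0.0172 CPM in Red River fish (SD, n = 6 and 6), a ratio of 2420 (1040 to 7460) resting on 5 Red River reads. It was also at 65.99 CPM in L3 and 21.96 in L5, and at most 0.02524 CPM in the other libraries labelled Delta Select channel. The transcript k86:801792 had 39.2 ± 13.2 against 0.02014 ± 0.0187 CPM, a ratio of 2050 (880 to 6330). It was also present in libraries labelled Delta Select channel, at 30.61 CPM in L3, 10.72 in L5, 16.67 in H5 and 10.02 in H9. It was not called in limma-voom (log2 fold change 10.46). In the other direction, k50:1937876 was at 0.358 ± 0.11 CPM in hybrids and 25.18 ± 24.6 CPM in Red River fish (log2 fold change -5.58 ± 0.63, edgeR adjusted p = 1.37e-05), and k86:812141 at 0.6957 ± 0.462 against 22.37 ± 11.1 CPM (-5.08 ± 0.83, adjusted p = 0.000323). In all, 23698 transcripts were higher and 20565 lower in hybrids. Differences above 16-fold were mostly rises, with 1406 higher and 82 lower. Within the low and the high temperature, 27991 and 29903 transcripts differed.

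Hybrids and fish labelled Delta Select channel catfish differed in 33693 transcripts, 18775 higher and 14918 lower in hybrids. The transcript k94:98188 had 66.59 ± 22 CPM in hybrids and 10.56 ± 17.6 CPM in Delta Select fish (SD, n = 6 and 6), and k82:855736 had 211.5 ± 28.3 against 26.35 ± 43.4 CPM. The Delta Select level of both came from L3 and L5, and leaving out these libraries raised their log2 fold changes from 7.27 to 11.33 and from 6.23 to 10.46. The transcript k82:616685 was lower in hybrids, at 1.483 ± 0.495 against 29.22 ± 19.6 CPM (log2 fold change -4.28 ± 0.89, edgeR adjusted p = 0.00284). The other fall named by the rule, k66:1869628, rested on H3, with 3879 CPM there and at most 49.74 CPM in any other library, and its log2 fold change went from -5.01 to -1.45 without H3, where it stayed called (adjusted p = 0.044). It was not called in limma-voom (-2.15), and DESeq2 gave it no adjusted p (-5.02). At the high temperature 28594 transcripts differed. There the median level of hybrid-restricted transcripts was at most 0.000271 in libraries labelled Delta Select, although 3.1% of these transcripts in H3, 6.2% in H5 and 5.43% in H9 were above 0.1 on that scale. At the low temperature, where L3 and L5 enter, 4286 differed.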

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

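A single result was flagged as a possible difference in temperature response between types, by an unadjusted p under 0.05. It came from a permutation test with the type means removed that was chosen after the data were seen. Interaction calls made by DESeq2, by limma-voom or without some libraries were not part of this flagging. On the 12432 transcripts called in Delta Select fish, the mean log2 change in the Delta Select direction was 0.5617 in Red River and 0.4774 in hybrid fish, a difference of 0.08429 ± 0.0371 (SE, 3 libraries per group). The permutation test gave a two-sided p of 0.035, which did not pass after adjustment over the 3 comparisons of this kind (0.105), and the exact permutation test without removal of the type means gave 0.61. All 3 Red River high-temperature libraries, at 0.518 to 0.617 above their low-temperature mean, lay above the 3 hybrid ones, at 0.4546 to 0.5011. The list was chosen with libraries L3 and L5, and no explanation was tested.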

How the results depend on the processing

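The alternatives that leave out L3 and L5, that leave out pairs of low-temperature libraries and that thin the libraries were chosen after the data were seen. Of 28 log2 fold changes of named transcripts, 15 stayed called under every alternative tried for them, 13 lost the call under at least 1, and 0 reversed. The fits with thinned libraries, without pairs other than L3 and L5, and without single libraries outside the compared groups were not among these alternatives. For 4 of the 28 changes DESeq2 gave no adjusted p and was not counted. The averaged temperature effect and the contrasts of hybrid against channel catfish stayed within 1.5 times under each alternative, except that a mean of at least 50 reads left fewer transcripts to test and gave 20238 calls for hybrid against Delta Select and 25194 for hybrid against Red River. Of the larger changes, limma-voom called 8930 transcripts for temperature in Red River and 18659 in Delta Select, and the cause was not tested. Fitting only the Delta Select libraries gave 2578 calls and leaving out L3 and L5 gave 2730. The joint interaction had 0 calls in edgeR, 1215 in DESeq2, 197 in limma-voom and 53 without L3 and L5. For Red River against Delta Select, DESeq2 called 4889, limma-voom 5779, the fit of only these groups 1656, the filter at a mean of 50 reads 1628, and the fit without L3 and L5 1022. The cause was not tested for DESeq2, for limma-voom or for the fits of only the compared groups. For the averaged temperature effect, rises outnumbered falls with TMM (10150 and 9435) but not with DESeq2 size factors (9477 and 10295), in DESeq2 (9729 and 11053), at a mean of at least 50 reads (7223 and 7995), without the 20 most abundant transcripts (9723 and 9972) or without any of H1, H2, H3, H5, H7, H8 and L8.

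Leaving out each library of the compared groups in turn gave 16849 to 22804 calls for the averaged temperature effect. It gave 3392 (without L6) to 4329 in Red River, 6104 (without L3) to 16713 (without L8) in Delta Select, and 1483 (without L4) to 2071 in hybrids. It gave 0 to 3363 (without L8) for the joint interaction and 1544 (without L6) to 7178 (without L8) for Red River against Delta Select. It gave 28701 to 37123 for hybrid against Delta Select, and 41071 to 41758 for hybrid against Red River. Without L8, the low-temperature Delta Select group held only L3 and L5. With 1 low-temperature library left in a single type, taken to vary like the other groups, Delta Select had 15937 (L3), 5734 (L5) and 2730 (L8) calls, Red River 1123 to 1661 and hybrids 363 to 672. With L3 and L5 left out as well, in 14 libraries against 16 in the fit with L8, the latter ranges were 1739 to 2378 and 765 to 1214. With 3 tanks per group, 34% of simulated 2-fold temperature changes in Delta Select and 8% of simulated 2-fold differences in the joint interaction were recovered. The test of gene lists and its alternatives were not run, because the identifiers carry no gene names.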

Other observations

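The tests of where the hybrid-restricted transcripts in L3 and L5 came from, the ratio of large rises to large falls in hybrids, and the fits with 1 low-temperature library left in every type were chosen after the results were seen. The correlation across transcripts and the tests of depth and of other splits of the libraries were set before their own results were seen. The thinned fits used for depth were still added after other results of these data had been seen. A few transcripts, picked after their values were seen as at least 20 CPM and 50 times the next library, were abundant in 1 library alone. There were 6 in L5 (together 0.898% of its reads), 1 in H3 (3879 CPM), 3 in H2 (up to 1309 CPM), 5 in H6 (up to 229.1 CPM) and 2 in H8 (up to 997.2 CPM), and 0 in each of the other libraries. Those in L5 include k66:1845628, k58:248466u and k58:1674560, at 1655, 1635 and 1642 CPM. Whether these come from 1 source was not determined. The share of reads in the row that names no transcript was lower at the high temperature, with means of 24.632% and 25.1091% (exact permutation test, two-sided p = 0.00337, 9 against 9 libraries).

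Libraries L3 and L5, labelled Delta Select channel catfish at the low temperature, carried hybrid-restricted transcripts at median levels of 0.7 and 0.284 of the hybrid mean. For these transcripts as a set, a trait of the Delta Select strain is argued against by its other libraries, where the highest median level was 0.000271. A minority of the set was present there, with 4.65% above 0.1 in L8. Their summed level was 404.3 CPM in L8 and 142.4 to 268.6 at the high temperature. It was 16.29 to 18.84 in Red River libraries, 3988 in L3 and 1834 in L5. A whole exchange with a hybrid library is argued against by the leading principal component. There the lowest score of a library labelled hybrid was 160.2, above L3 (122.4) and L5 (34.33). Hybrid RNA within the pools is a candidate explanation. A set of 594 transcripts lower in hybrids than in both channel strains gave a share of 0.792 in L3 (quartiles 0.646 and 0.934), within 0.15 of the first estimate. For L5 they gave 0.482, further from 0.284 than that. However, L8, with a median level of 0 for hybrid-restricted transcripts, also gave 0.192 (quartiles -0.104 and 0.523), an offset above 0.15. The size of the share therefore stays open in both L3 and L5. A pool of 3 fish with 1 hybrid would give 0.33 and with 2 hybrids 0.67, but mixing of RNA or libraries at a later step may give such values too and was not tested.

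More transcripts were called for temperature in Delta Select (12432) than in Red River (5890) or hybrid fish (2855), while without L3 and L5, with L8 alone in its group, the counts were 2730, 7550 and 3915. Hybrid RNA in L3 and L5 may account for much of this. Across transcripts, the Delta Select temperature change fell with the hybrid minus Red River difference at the high temperature, which shares no library with it (Spearman correlation -0.48), and the value was -0.0478 without L3 and L5. Of transcripts that differed between hybrid and Red River fish 19.0% were called in Delta Select, against 8.39% of those alike in both. Red River gave 5.99% and 7.03%, and hybrid fish 3.24% and 3.22%. Alike here means not called between hybrid and Red River fish, with a small log2 fold change. Among these, Delta Select and Red River both gave a higher share than hybrid fish. Each share rests on its own contrast's adjusted p, whose cutoff loosens as the contrast has more calls. Calls due to hybrid RNA would thus raise the Delta Select share here too, so these shares cannot tell whether hybrid RNA explains the excess. A larger response of Delta Select fish stays open. With 1 low-temperature library left in every type and L8 in Delta Select, 9 fits gave a median of 2004 calls in Delta Select. This was above the hybrid count of the same fit in all 9, but above the Red River count in only 6 of 9. The fits are not separate comparisons, since all used L8, and Red River was ahead only where L6 was left. On transcripts called in hybrids, the mean log2 change was 1.197 in Red River and 1.094 in Delta Select fish, or 1.115 against L8 alone.

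A large part of the transcripts tested differed between hybrid and channel catfish, 44263 of them between hybrid and Red River fish. Depth is argued against as the whole cause, because with all libraries thinned to 1 depth 42802 were still called. The division of reads between assembled transcripts of channel and blue catfish origin may contribute. A hybrid keeps a channel copy of each gene, so this would give large rises and few large falls, and rises over 16-fold outnumbered falls over 16-fold by 17.1 to 1. Differences in expression of a gene as a whole between the types were not tested, since the transcripts could not be grouped into genes here.

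Each count of calls was set beside other splits of the same libraries. For the averaged temperature effect 1 of 60 splits, the real one, gave as many transcripts (19585, highest other 1829). The real split was also the only one of 40 to do so in each type contrast. The counts were 2710 against 315 for Red River and Delta Select, 33693 against 26219 for hybrid and Delta Select, and 44263 against 8818 for hybrid and Red River. A wrong split mixes real differences into its groups, which can lower its count. These splits therefore only rank the real count highest among those tried. The 26219 came from a split that put L3 among the hybrids in place of L4. Within a type 10 splits are too few to reach a share under 0.05, and the real and highest other counts were 5890 and 9 in Red River, 12432 and 590 in Delta Select, and 2855 and 7 in hybrids. For the joint interaction the real count was 0, so all 40 splits gave as many. Of these, 1 gave 32390, which points to a structure of the libraries. It placed the channel catfish libraries H1, H7, H9 and L8 and the hybrid libraries L4 and L7 under the hybrid name.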
